A study of Mus musculus with 3 samples.

How the data were processed

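Single cells of dorsal cortex from mouse pups were profiled with 10x Genomics 3' libraries, 1 library for each of 3 genotypes. The control carried floxed Map2k1 and Map2k2, which encode the kinases MEK1 and MEK2 that phosphorylate ERK. The Emx1-Cre mutant and the hGFAP-Cre mutant carried the same floxed genes with Cre driven by Emx1, active in cortical progenitors from early neurogenesis, or by the human GFAP promoter, active in radial glia later in gestation. Per the labels' protocols, FlashTag, a dye that marks cells dividing at the ventricle, was injected at embryonic day 18.0, dorsal cortices were taken at postnatal day 2, and tdTomato-positive cells were sorted. The protocol does not name the allele that carries tdTomato or say whether the dye was part of the gate, so which cells the sort took in from each genotype is open.

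The deposited values are raw UMI counts per gene and barcode. Per the file headers they were made by the authors with Cell Ranger 5.0.0, and per the submitters' processing notes with genome build mm10. All values were whole numbers, and the 27998 gene identifiers were alike in the 3 libraries, with no entry for Cre or tdTomato. The files list called barcodes. The lowest UMI count of a barcode was 500 in the control, 2644 in the Emx1-Cre library and 3065 in the hGFAP-Cre library, so cells had not been called at a like depth.

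Cells with at least 1000 detected genes and under 10% mitochondrial counts were kept. Doublets predicted by Scrublet as implemented in scanpy 1.11.5 were removed, with an expected rate of 10% and the threshold it set in each library. These calls took out 4.49% of control, 7.39% of Emx1-Cre and 8.18% of hGFAP-Cre barcodes, and 9491, 12225 and 12060 cells remained. Counts were log-normalised, 2000 variable genes were chosen across libraries, and 30 principal components gave a graph of 15 nearest neighbours, clustered by the Leiden method (leidenalg 0.10.2) at resolution 1. The ERK response genes, immediate early genes, Map2k1, Map2k2, sex-linked, mitochondrial, ribosomal and haemoglobin genes were kept out of the variable genes. No batch correction was applied, since library and genotype are the same thing here. Other tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, scikit-learn 1.9.0 and igraph 0.11.9.

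Clusters were named from 18 lists of cell type markers fixed before the data were examined. A marker counted as raised when its mean was at least 2-fold that of all other cells and at least 25% of the cluster had a UMI of it. A cluster took the name of the class with the most raised markers and stayed unnamed with fewer than 3, when its 10 top genes held more markers of another class, or when it had a low UMI count and no own marker among them. Ties went to the higher mean fold. This naming rule was not fixed beforehand: it was chosen after the clusters were seen, out of 3 candidate rules, and the shares under naming by mean fold stand beside the main ones. Of 36 clusters, 32 were named, in 12 classes, and 4 stayed unnamed. No cluster was named radial glia-like, and the astrocyte-like clusters also had raised radial glia markers, so this class holds both kinds of glia.

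Each class share has an exact Clopper-Pearson 95% interval. Counts were summed per class and library and given as CPM, each gene's share of the summed UMIs on the usual CPM scale, with exact Poisson 95% intervals. A log2 ratio of a mutant over the control used a pseudocount of 5 CPM. Intervals cover counting error only: with 1 library per genotype there is no replicate, so no test between genotypes was made and no p-value is given. The limit that a count of 0 allows was set at 3 counts. The 16 gene lists, fixed before the data were examined, were ERK response, ERK cascade components, receptor tyrosine kinases, SHH pathway, NOTCH pathway, BMP and ID genes, WNT pathway, astrocyte maturation, oligodendrocyte lineage, interneuron lineage transcription factors, cholesterol synthesis, S phase, G2/M phase, immediate early and dissociation, p53 and apoptosis, and interferon response. A list's value is the median log2 ratio of its members at 10 CPM or more in either library, with an interval from 2000 redraws of the counts and its percentile among 10000 random lists matched on mean expression. Members are called higher or lower from a 1.5-fold difference on.

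Genes are named by a rule fixed beforehand, in classes with at least 100 cells in every library among the glial and interneuron classes, which left the astrocyte-like class. The rule took Map2k1 and Map2k2, up to 4 members per described list with the largest log2 ratio, and outside the lists the 5 highest and 5 lowest genes at 50 CPM or more whose intervals lay apart. It left out sex-linked, mitochondrial, ribosomal, haemoglobin and unnamed predicted genes. Which lists are described with their genes was settled after the values were seen, and genes named outside this rule are said to be so. Results that need items withheld for evaluation were left out. Gene coordinates are from the GENCODE annotation of GRCm38, the build that mm10 names, in which 27645 of the 27998 identifiers were found.

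The steps were tested on simulated data. Counts for the astrocyte-like class were drawn from the control's means with 200 genes changed. In the Emx1-Cre simulation over 3157 genes, the intervals lay apart in the right direction for 71 of 71 genes changed 1.5-fold, 66 of 66 changed 2-fold and 63 of 63 changed 4-fold. Among 2957 unchanged genes the intervals also lay apart for 592, of which 0 reached 1.5-fold; the cause was not tested. In the hGFAP-Cre simulation over 3157 genes these values were 83 of 83, 62 of 62 and 55 of 55, with 58 of 2957 unchanged genes apart. Intervals apart together with a measured difference of 1.5-fold or more were reached by only 42.3% and 21.7% of the genes changed 1.5-fold. Lists were drawn from 8124 genes in the Emx1-Cre and 8179 in the hGFAP-Cre simulation: of 200 lists lowered 2-fold, 200 lay under the 5th percentile in each, against 5 and 6 of 200 unchanged lists. The simulated libraries differed only by counting error and the changed genes, with no difference in cluster makeup and no genes that vary together. These rates therefore do not carry over to the real comparisons. In real Emx1-Cre astrocyte-like cells most lists lay at very low or very high percentiles.

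Alternatives set before the data were examined were a minimum of 2000 genes, mitochondrial counts under 5%, doublets kept, resolutions of 0.5 and 2, values centred per library, each library clustered alone, cells called 1 by 1 after thinning to 2000 UMIs, other denominators, pseudocounts of 1 and 20 CPM, other list minimums, scaling by the median ratio, thinned cells, and cells without Mki67 and Top2a counts. Added after seeing the data were 1 UMI floor for all libraries, naming by mean fold, shares without Cajal-Retzius-like and ependymal-like cells, and pairs of classes joined.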

Results

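The data are UMI counts of single cells sorted from the dorsal cortex of mouse pups at postnatal day 2, in 3 libraries: a control, an Emx1-Cre mutant and an hGFAP-Cre mutant of Map2k1 and Map2k2, with 1 library each and so no replicate. The control held 11886 barcodes and 85480826 UMIs, the Emx1-Cre mutant 13214 barcodes and 84016524 UMIs, and the hGFAP-Cre mutant 13139 barcodes and 89917586 UMIs. After filtering, the median cell had 6421 UMIs in the control, 4998 in the Emx1-Cre library and 5318 in the hGFAP-Cre library. The study's title concerns how NOTCH, ERK and SHH signalling direct cortical progenitors to astrocytes, oligodendrocytes and olfactory bulb interneurons. The comparisons below address the ERK part: which cell classes and which genes differed when its upstream kinases were targeted.

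Map2k1 (ENSMUSG00000004936, GRCm38 chromosome 9, 64185770 to 64253631) was at 16.6 CPM (95% interval 15.7 to 17.5) in the control, 14.0 (13.1 to 14.8) in the Emx1-Cre and 16.3 (15.4 to 17.2) in the hGFAP-Cre library. Map2k2 (ENSMUSG00000035027, chromosome 10, 81105915 to 81133975) was at 196.5, 217.2 and 214.3 CPM. In astrocyte-like cells Map2k1 was at 20.2, 15.8 and 24.6 CPM and Map2k2 at 187.5, 182.6 and 235.5 CPM. These 3' tags lie at the end of the transcripts and need not fall in the deleted part, so they check neither the deletion nor the labels. Xist, the RNA that silences an X chromosome in females, was at 1460.4 CPM in the control, 0.122 in the Emx1-Cre and 0.95 in the hGFAP-Cre library, while the Y-linked Ddx3y was at 0 counts (up to 0.0390 CPM), 37.3 and 45.6 CPM. The control cells thus came from a female source and both mutants from male ones, and sex differs with genotype in every comparison below.

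In the Emx1-Cre mutant, cells of the olfactory bulb interneuron lineage were far scarcer than in the control and oligodendrocyte precursor-like cells more frequent. The interneuron lineage class, marked by Dlx, Gad and Sp8 genes, made up 0.810% of kept cells (0.659% to 0.985%, 99 cells) against 11.6% (11.0% to 12.3%, 1102 cells) in the control, 14.3-fold lower. Oligodendrocyte precursor-like cells, marked by Pdgfra and Sox10, made up 2.24% (1.99% to 2.52%, 274 cells) against 0.685% (0.529% to 0.872%, 65 cells), 3.27-fold higher. Multipotent progenitor-like cells, marked by Egfr, Olig1 and Olig2, were at 0.286% against 4.45%, 15.5-fold lower. Astrocyte-like cells were at 16.5% (15.9% to 17.2%) against 24.5% (23.6% to 25.4%), a log2 ratio of −0.57.

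Classes outside these lineages differed too. Upper-layer projection neuron-like cells were at 5.96% in the Emx1-Cre mutant against 42.7%, and excitatory intermediate progenitor-like cells, marked by Eomes and Neurog2, at 17.96% against 9.21%. Cajal-Retzius-like cells, the Reln-expressing neurons of the cortical surface, were at 11.6% against 1.12%, ependymal-like cells at 9.87% against 0.337%, deep-layer projection neuron-like cells at 5.87% against 0.495% and mural-like cells at 1.60% against 0.379%. Microglia-like cells were at 2.02% against 2.57% and endothelial-like cells at 0.376% against 1.11%. Unnamed clusters held 24.9% of Emx1-Cre cells and 0.917% of control cells, most of them in a single cluster with Cck, Grp and Neurod6 among its top genes, whose only raised marker was one of upper-layer neurons. The upper-layer share reversed, to a log2 ratio of 1.17, with each library clustered alone.

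The astrocyte-like and interneuron directions depend on how clusters are named: by mean fold, the Emx1-Cre log2 ratio was 0.68 for astrocyte-like and 0.83 for interneuron lineage-like cells, against −0.57 and −3.84. Joined with clusters then named radial glia-like and cortical interneuron-like, the values were −0.57 and −3.51. When oligodendrocyte precursor-like and multipotent progenitor-like cells are joined, they were at 2.53% in the Emx1-Cre mutant against 5.13%, a log2 ratio of −1.02 in place of 1.71, and with at least 2000 genes per cell the precursor value was 0.43, with each library clustered alone 0.63 and with cells called 1 by 1 it was 0.45.

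**Figure D1:**
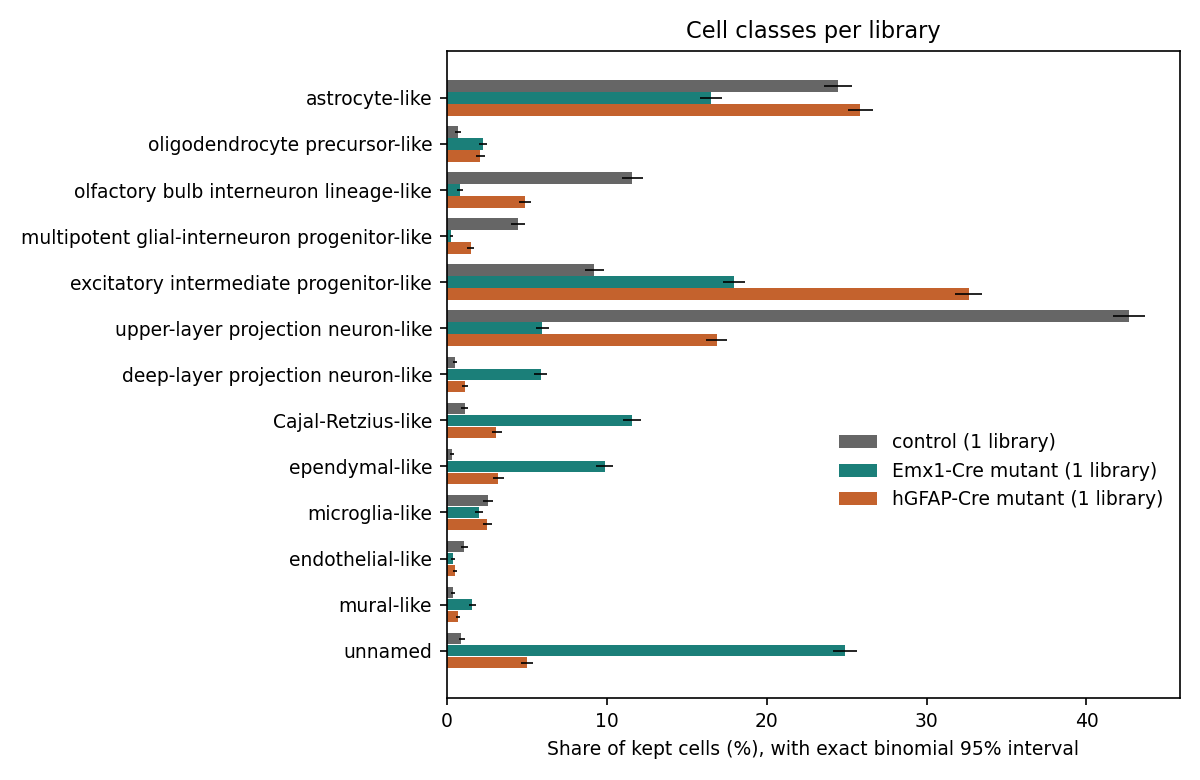
Share of kept cells in each class (horizontal axis, percent) for the control, the Emx1-Cre mutant and the hGFAP-Cre mutant, 1 library each; lines are exact binomial 95% intervals and cover counting error only. Interneuron lineage-like cells are at 11.6%, 0.810% and 4.89%, and oligodendrocyte precursor-like cells at 0.685%, 2.24% and 2.10%.

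In astrocyte-like cells of the Emx1-Cre mutant, genes of the SHH and NOTCH pathways and of astrocyte maturation were lower than in the control, while the ERK response list did not stand apart from other genes. Its median log2 ratio was −0.25 (−0.36 to −0.21), at percentile 64.9 of matched random lists, and the median over all genes at 10 CPM or more was itself −0.29 in this comparison. Of the 17 measured ERK response members 6 were lower, 4 higher and 7 between. Epha4, an ephrin receptor, was at 43.8 against 149 CPM (log2 ratio −1.65), whereas Ier3, an ERK-induced survival factor (1.62), Spry1, a feedback inhibitor of receptor tyrosine kinase signalling (1.62), and the transcription factor Myc (1.13) were higher. The ERK cascade components had a median of −0.36 (percentile 37.4).

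Among SHH pathway genes 8 of 9 were lower (median −1.54, percentile 0). The SHH co-receptor Gas1 (chromosome 13, 60174405 to 60177365) was at 38.1 against 543.9 CPM, 14.3-fold lower. The co-receptors Cdon (−2.49) and Boc (−1.76) and the SHH effector Gli1 (−1.68) were lower as well. In the NOTCH pathway 9 of 14 members were lower (median −0.88, percentile 0.01), among them the receptor Notch2 (−1.67), the ligand Dll1 (−1.38) and the neurogenic factor Hes6 (−1.27), while the NOTCH target Heyl was higher (1.83). Of 13 astrocyte maturation genes 7 were lower (median −0.80, percentile 0): the glutamate transporter Slc1a2 (−1.82), clusterin, Clu (−1.82), and the glycolytic enzyme Aldoc (−1.24), against a higher Id3 (1.79), a BMP-induced inhibitor of differentiation at 3141 against 905.3 CPM.

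All 5 measured oligodendrocyte lineage genes were lower in these cells (median −1.16, percentile 0.46), with Pcdh15 at −1.72, Olig2 at −1.16 and Olig1, both regulators of oligodendrocyte fate, at −1.12. Receptor tyrosine kinases had a median of −0.97 (percentile 0.255), led by Egfr (−1.62), Igf1r (−1.38) and Fgfr1 (−1.36). The interneuron lineage transcription factors (−0.95, percentile 0.715), cholesterol synthesis (−0.68, percentile 0.24) and immediate early and dissociation lists (−0.45, percentile 1.4) were also low. The S phase (0.28, percentile 99.99), G2/M phase (0.13, percentile 98.3), p53 and apoptosis (0.11, percentile 98.2) and interferon response lists (1.27, 4 members) were high against matched lists, although only 2 of 19, 5 of 20, 3 of 10 and 2 of 4 members were at least 1.5-fold higher, with the mitotic genes Ube2c (1.05) and Birc5 (0.96) and the p53 targets Phlda3 (2.57) and Cdkn1a (1.39) above the control. The last 3 lists are not stable: G2/M was at −0.11 at resolution 2, p53 at −0.13 in thinned cells and interferon at −0.0280 over all detected members. BMP and ID genes (−0.05, percentile 72.6) and the WNT pathway (−0.17, percentile 89.0) did not stand apart.

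Outside the lists the highest genes in the Emx1-Cre astrocyte-like cells were Plvap (3.42), a protein of fenestrated endothelium, the actin-binding Tagln (3.34), S100a10 (3.27), the hyaluronan synthase Has2 (2.73) and the small GTPase Rasl11a (2.43). The lowest were Tmem132b (−3.76), the WNT inhibitor Sfrp1 (−3.68), Fstl5 (−3.33), the GABA receptor subunit Gabrb1 (−3.13) and Veph1 (−3.04). The class is not made of the same clusters in each library: 60.2% of control cells lay in a cluster with 0 Emx1-Cre cells, and 52.9% of Emx1-Cre cells in another that held 1.12% of the control's. Gas1, Slc1a2 and Aldoc were among the top genes of the first cluster, and Id3, Tagln and Has2 among those of the second. The SHH, NOTCH and astrocyte maturation lists were not split by cluster. Their values may therefore reflect which clusters a library holds, and a change within like cells cannot be told apart from this. Cells with a UMI of Mki67 or Top2a made up 46.0% (43.8% to 48.2%) of the class in the Emx1-Cre library and 24.2% (22.5% to 26.0%) in the control.

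In the hGFAP-Cre mutant, oligodendrocyte precursor-like cells were again more frequent and interneuron lineage-like cells scarcer than in the control, by less than in the Emx1-Cre mutant for the latter. Oligodendrocyte precursor-like cells were at 2.10% (1.85% to 2.37%, 253 cells), 3.06-fold higher. Interneuron lineage-like cells were at 4.89% (4.51% to 5.29%, 590 cells), 2.37-fold lower, and multipotent progenitor-like cells at 1.49%, 2.98-fold lower. Astrocyte-like cells were at 25.9% (25.1% to 26.7%), a log2 ratio of 0.08 over the control.

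Excitatory intermediate progenitor-like cells were at 32.6% of the hGFAP-Cre library, 3.54-fold higher than in the control, and upper-layer projection neuron-like cells at 16.9%, 2.53-fold lower. Cajal-Retzius-like cells were at 3.11%, ependymal-like cells at 3.23%, deep-layer projection neuron-like cells at 1.12% and mural-like cells at 0.688%, all above the control, with microglia-like cells at 2.53% and endothelial-like cells at 0.489%. The direction of the astrocyte-like share is not stable: its log2 ratio was −0.60 with mitochondrial counts under 5%, −1.51 with doublets kept, −4.17 at resolution 2 and −2.94 with clusters named by mean fold. With doublets kept and at resolution 2, 2291 and 2662 hGFAP-Cre cells with most raised markers of astrocytes stayed unnamed. Interneuron lineage-like cells were at 0.21 with at least 2000 genes per cell and 3.10 with naming by mean fold, in place of −1.25. Under naming by mean fold the values were 0.08 for astrocyte-like joined with radial glia-like and −0.91 for interneuron lineage-like joined with cortical interneuron-like cells. With all choices as in the main analysis, oligodendrocyte precursor-like and multipotent progenitor-like cells together were at −0.52 in place of 1.62, with 3.59% of cells against 5.13%. With each library clustered alone the precursor log2 ratio was 0.65 and the upper-layer one, reversed, 0.64, and with cells called 1 by 1 the precursor one was 0.52.

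In astrocyte-like cells of the hGFAP-Cre mutant, ERK response and cell cycle genes were lower than in the control and p53 targets higher. The ERK response list had a median log2 ratio of −1.23 (−1.37 to −1.08), at percentile 0 of matched random lists, with 10 of 15 measured members lower, 1 higher and 4 between. The ETS factors through which ERK and FGF signals act on transcription were lowest: Etv4 (chromosome 11, 101769742 to 101785371) was at 10.9 (9.58 to 12.4) against 79.6 CPM (76.0 to 83.4), 7.28-fold lower, Etv5 at 14.8 against 85.5 CPM, 5.78-fold lower, and Etv1 at 23.7 against 101 CPM, 4.25-fold lower. The feedback inhibitor Spry2 was at 72.0 against 262.3 CPM, 3.64-fold lower. The ERK cascade components had a median of −0.06 (percentile 52.5).

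All 20 G2/M phase genes were lower (median −2.18, percentile 0), among them Top2a (−2.88), Cenpf (−2.83) and the proliferation marker Mki67 (−2.71), and so were 15 of 19 S phase genes (median −0.87, percentile 0). At resolution 2 both lists reversed, to 0.14 and 0.44. There 2662 hGFAP-Cre cells with most raised markers of astrocytes stayed unnamed, so the class kept far fewer cells. With the main choices both lists were low outside the Cre lineage too: G2/M medians were −2.90 in 59 endothelial-like and −2.61 in 83 mural-like cells of this library, and S phase medians −1.32 and −1.25. The control held 105 endothelial-like and 36 mural-like cells. Of 12 p53 and apoptosis genes 10 were higher (median 1.28, percentile 100). The cell cycle inhibitor Cdkn1a (chromosome 17, 29090976 to 29100727) was at 422 (414 to 431) against 9.56 CPM (8.33 to 10.9), 44.1-fold higher, and the p53 targets Phlda3 (3.28), Bbc3, a trigger of apoptosis (2.01), and Ccng1 (1.85) were higher too. The interferon response list was at 1.90 over 5 members (percentile 99.98).

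SHH pathway genes were lower in the hGFAP-Cre mutant as well (5 of 9, median −0.61, percentile 0.235), with Gas1 at −1.63 and Gli2 at −0.92. The NOTCH pathway list did not stand apart (−0.19, percentile 16.3), although the NOTCH effectors Hes1 (−1.53) and Hes5 (−1.09) were lower. Astrocyte maturation genes were lower in 7 of 13 and higher in 3 (median −0.61, percentile 0.02): the fatty acid ligase Acsbg1 (−1.37), Slc1a2 (−1.16) and Sparcl1, a secreted synapse-promoting protein (−1.11), were lower and Id3 (1.10) higher. Olig1 (−3.07) and Olig2 (−2.73) led the oligodendrocyte lineage list (−1.18, percentile 0.02). Receptor tyrosine kinases had a median of −0.59 (percentile 1.43), with Egfr 6.01-fold lower and the neurotrophin receptor Ntrk2 2.11-fold higher. At resolution 2, where the class kept far fewer hGFAP-Cre cells, Olig2 and Ntrk2 reversed, to 0.0371 and −0.40.

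The immediate early and dissociation list was at −0.47 (percentile 0.03), with the ERK-dependent Egr1 at 25.3 against 648 CPM (−4.43), Nr4a1 at −2.92 and Ier2 at −2.84. Interneuron lineage transcription factors were at −0.82 (percentile 0.51), BMP and ID genes at −0.17 (percentile 15.3), the WNT pathway at −0.34 (percentile 7.1) and cholesterol synthesis at −0.01 (percentile 48.1). Outside the lists the highest genes were Prm1, a sperm protamine with 38218 counts against 0 in the control, the small heat shock protein Cryab (4.4), Nme5 (3.29) and Rsph1 (3.07), both found in cilia, and Anxa2 (3.03). The lowest were the glutamate receptor Grm5 (−2.84), the splicing factor Cwc22 (−2.68), the histone gene Hist1h2ap (−2.68), the thyroid hormone deiodinase Dio2 (−2.57) and the cytokinesis factor Prc1 (−2.54). Of the class 66.5% lay in a cluster that held 0.775% of the control's astrocyte-like cells, and 27.2% in another that held 0.560%. Prm1 was among the top genes of both clusters and was not kept out of the variable genes. Whether it helped to set these cells apart from the control's was not tested. Of the hGFAP-Cre astrocyte-like cells, 8.92% (7.94% to 9.97%) had a UMI of Mki67 or Top2a. The ERK response median was −0.41 at resolution 2, where the class kept far fewer hGFAP-Cre cells, and −0.67 with a pseudocount of 20 CPM.

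**Figure D2:**
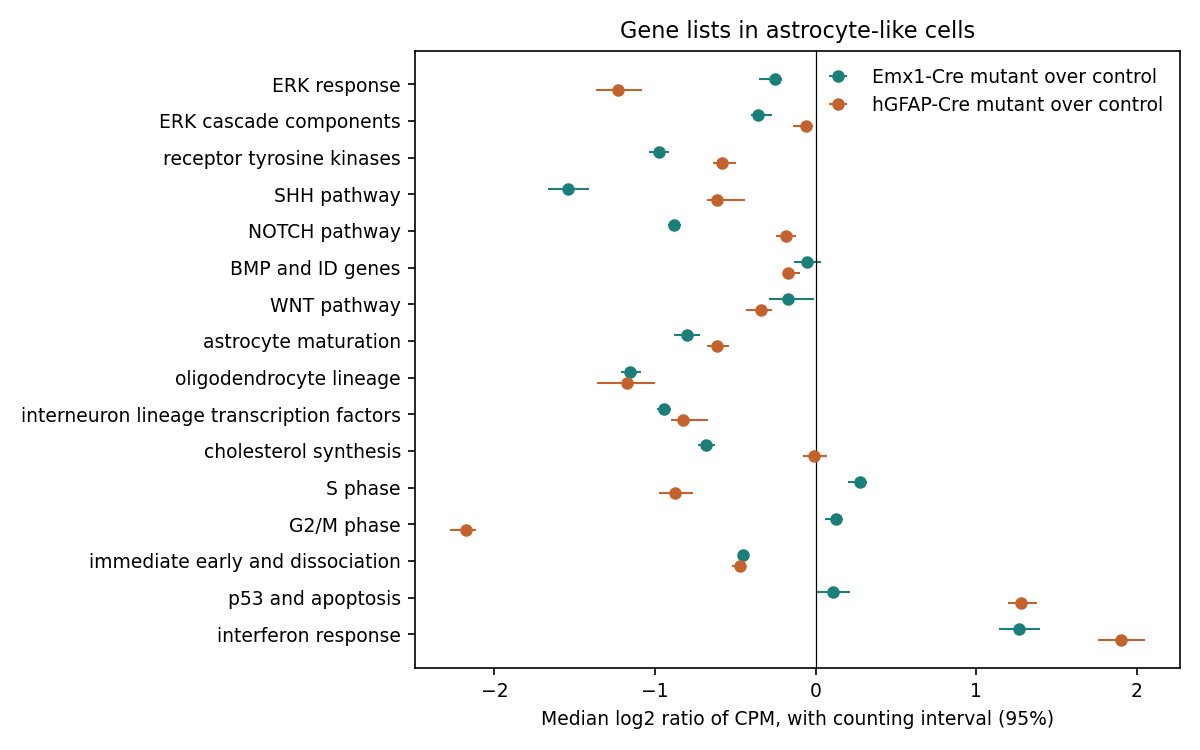
Median log2 ratio of CPM in astrocyte-like cells, mutant over control (horizontal axis), for each of the 16 gene lists (vertical axis); lines are 95% counting intervals. The ERK response list is at −0.25 in the Emx1-Cre and −1.23 in the hGFAP-Cre mutant, and the G2/M phase list at 0.13 and −2.18.

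Side by side, 5 ERK response members of 17 were at least 1.5-fold lower in both mutants: Etv4, Etv5, Spred2, Spred3 and Spry4, the last 3 feedback inhibitors of the pathway, of which all but Etv4 and Etv5 are named here after their values were seen. Independent lists of the same sizes would share 3.88, and unchanged libraries simulated against the shared control 0. In the SHH pathway 5 genes were lower in both (Boc, Gas1, Gli1, Gli2 and Ptch1), against 4.44 for independent lists and 0 in the simulation, and in the NOTCH pathway 3 (Dll1, Hes1 and Hes5), against 1.93 and 0. With 1 control library it cannot be split, and part of any excess can come from the shared control. The difference between the mutants in the ERK response list was not tested.

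Oligodendrocyte precursor-like cells had an ERK response median of −0.11 (−0.32 to 0.15) in the Emx1-Cre and −0.41 (−0.62 to −0.08) in the hGFAP-Cre mutant, where 3 of 15 and 6 of 15 members were lower; the control held only 65 such cells. In upper-layer projection neuron-like cells the medians were −0.95 and −0.59, in interneuron lineage-like cells −0.82 and −0.74, and in excitatory intermediate progenitor-like cells −1.20 and −0.23, the latter at percentile 32.6. Multipotent progenitor-like cells did not stand apart, at −0.29 (percentile 54.5, 35 Emx1-Cre cells) and −0.15 (percentile 46.2). These classes too are made of different clusters: a cycling cluster held 23.2% of control, 3.03% of Emx1-Cre and 11.5% of hGFAP-Cre interneuron lineage-like cells, and another held 65.7% of Emx1-Cre and 0.593% of control upper-layer cells. Microglia-like cells, which neither Cre line should recombine, were at 0.03 (−0.18 to 0.27) and 0.07 (−0.14 to 0.23).

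**Figure D3:**
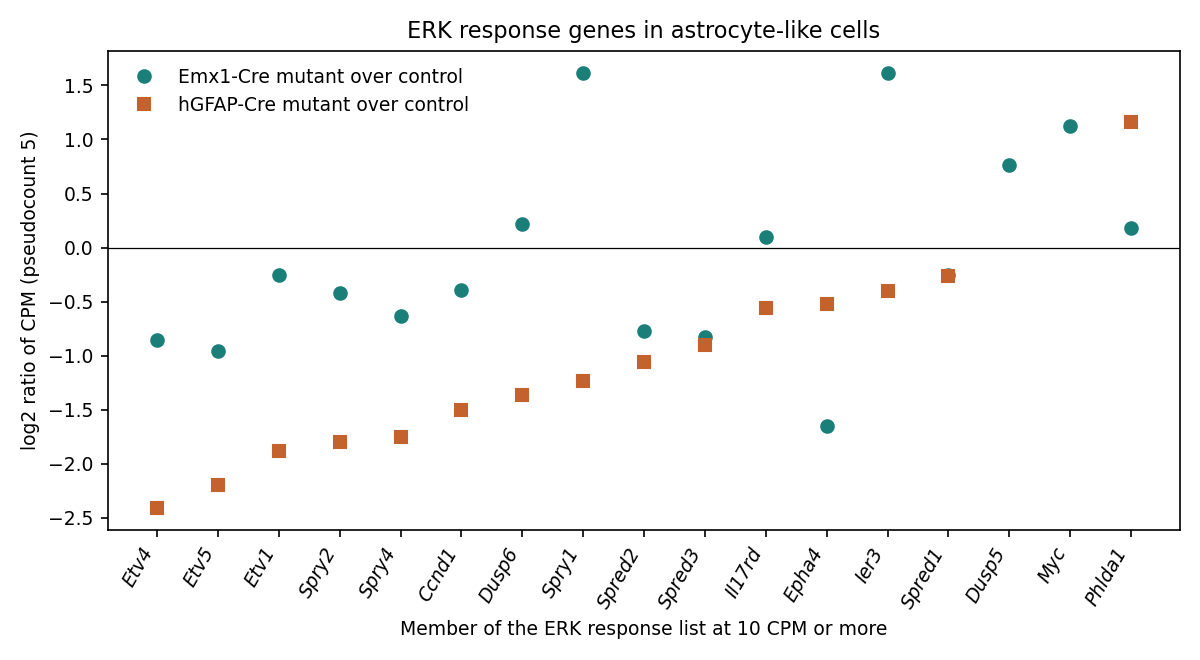
log2 ratio of CPM (vertical axis) in astrocyte-like cells for each ERK response gene at 10 CPM or more in either library of a comparison (horizontal axis), with circles for the Emx1-Cre and squares for the hGFAP-Cre mutant over the control. Etv4 and Etv5 lie at −2.41 and −2.19 in the hGFAP-Cre mutant and at −0.85 and −0.96 in the Emx1-Cre mutant, while Spry1 lies at −1.23 and 1.62.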

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

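Of the tests here, those of the lower UMI floor and of male germ cells were set before their results were seen; all others were chosen after the result was seen: kept ERK activity, sorting, placement in another cluster, free RNA, the transgene tail, dissociation state, cell makeup, sex, and loss of Map2k1 and Map2k2.

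Oligodendrocyte precursor-like cells were more frequent in both mutants than in the control (log2 ratios 1.71 and 1.62), opposite to what the study's title leads one to look for. The lower UMI floor of the control, taken alone, is argued against: with 1 floor for all libraries the log2 ratios kept at least 0.868 of their size, so most of the difference remains. Depth in general is not settled by this. Emx1-Cre precursor-like cells had a median of 3604 UMIs against 7918 in the control. With at least 2000 genes per cell their ratio was much smaller, as given above, while the hGFAP-Cre ratio was not. Sorting that took in more cell types in the mutants stays open, as 2 of the 4 classes set out for it (mural-like and Cajal-Retzius-like, but not endothelial-like and microglia-like) were at least 1.5-fold more frequent in both. Cajal-Retzius-like cells are cortical neurons that need not lie outside the Cre lineages, so their share says little about a sort by Cre lineage. It could bear on a sort by the dye, and whether the dye was part of the gate is not known. Deep-layer projection neuron-like cells, not among the 4 classes, were also more frequent in both mutants, 11.84- and 2.26-fold. Of the classes outside the Cre lineages only mural-like cells were more frequent in both. Precursors placed in another cluster in the control stay open: together with multipotent progenitor-like cells the log2 ratios were −1.02 and −0.52, as set out for this explanation. That outcome cannot decide it. The control held 422 multipotent progenitor-like beside 65 precursor-like cells, so the scarcer progenitor class sets the sign wherever precursors were placed. Cells called 1 by 1 still gave 0.45 and 0.52. Cells that kept ERK activity stay open too, since the Emx1-Cre ERK response median of −0.11 in these cells lay on the side set out for this explanation and the hGFAP-Cre median of −0.41 between the bounds, and the sex of the pups differs in the same way as the genotype.

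Prm1, a gene of maturing sperm outside the gene lists, had 44147 counts (566.6 CPM) in the hGFAP-Cre library, 3 in the Emx1-Cre library and 0 in the control. Free RNA in the droplets as the main source is argued against by 11.96 CPM (7.81 to 17.5) in microglia-like cells of that library beside 1787 in astrocyte-like cells. Endothelial-like cells were at 68.3 CPM (47.0 to 95.9) and mural-like cells at 56.4 (34.9 to 86.2), so a smaller part from free RNA is not excluded. Male germ cells are argued against by 2 summed counts of Prm2, Tnp1 and Tnp2. A candidate explanation is the tail of a Cre transgene, since protamine sequence is used as a 3' end in some Cre constructs, and the level was highest in astrocyte-like cells; the 3 counts in the Emx1-Cre library, where 0 was predicted, keep it open, and the construct is not given in the labels.

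A lower ERK response list in astrocyte-like cells of both mutants was looked for as the expected effect, and it did not hold: against matched lists the Emx1-Cre median lay at percentile 64.9 and the hGFAP-Cre median at percentile 0. Loss of Map2k1 and Map2k2 stays open in both mutants, since these percentiles restate the pattern and the list was low in other Emx1-Cre classes, at −1.20 in excitatory intermediate progenitor-like cells. The makeup of that class differs too: a cluster with 69.5% of its control cells held 4.46% of its Emx1-Cre cells. Cell makeup of the astrocyte-like class stays open as well: upper-layer projection neuron-like cells, with medians of −0.95 and −0.59, are themselves made of different clusters in each library. Dissociation state cannot be told apart: the immediate early list was at −0.45 and −0.47, further down than the ERK response list in the Emx1-Cre mutant and less than in the hGFAP-Cre mutant, and several of its genes are ERK targets themselves. The sex of the pups cannot be told apart from genotype, with Xist at 1460.4 CPM in the control and under 1 CPM in both mutants.

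The mutants went in opposite directions for the astrocyte-like share (log2 ratios −0.57 in the Emx1-Cre and 0.0790 in the hGFAP-Cre mutant), a difference that was not tested and that changes with the processing. The S phase list in astrocyte-like cells was at 0.28 in the Emx1-Cre and −0.87 in the hGFAP-Cre mutant, and the G2/M phase list at 0.13 and −2.18, also untested. Y-linked genes, not used in the comparisons, were present in both mutants and at or near 0 in the control: Ddx3y at 37.3 CPM in the Emx1-Cre and 45.6 in the hGFAP-Cre library, and Eif2s3y at 53.9 and 79.2.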

How the results depend on the processing

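Alternatives set before the data were examined and those added after seeing the data are both given here, the latter named as added; no paired analysis was possible because each genotype has 1 library. Values are log2 ratios, Emx1-Cre first and hGFAP-Cre second unless named, and the cause of a move was not tested. With the main choices, oligodendrocyte precursor-like shares were at 1.71 and 1.62, astrocyte-like at −0.57 and 0.08, interneuron lineage-like at −3.84 and −1.25, and the ERK response list at −0.25 and −1.23. The direction of the astrocyte-like share changed with many choices, that of the precursor share only when joined with multipotent progenitor-like cells, and the hGFAP-Cre ERK response median stayed under 0 throughout. With at least 2000 genes, precursors were at 0.43 and 2.03, astrocyte-like cells at −0.88 and 0.30, and interneuron lineage-like cells at −2.86 and, reversed, 0.21 (also 0.21 together with cortical interneurons). With mitochondrial counts under 5%, astrocyte-like cells were at −0.69 and, reversed, −0.60, and interneuron lineage-like cells at −3.50 in the Emx1-Cre mutant. With doublets kept, the hGFAP-Cre values were −1.51 for astrocyte-like cells (reversed, and the same with radial glia), −1.40 for interneuron lineage-like cells, −0.90 for the ERK response list and 0.54 for Ier3 (reversed). At resolution 2, astrocyte-like cells were at −0.85 and, reversed, −4.17 (−4.23 with radial glia), interneuron lineage-like cells at −3.38 and −0.83, the ERK response list at −0.18 and −0.41, and the G2/M phase list, reversed, at −0.11 and 0.14. There the hGFAP-Cre S phase list was at 0.44, and reversed genes were Ccnd1 at 0.11, Dll1 at 0.26, Dusp6 at 0.40, Fgfr2 at −0.37, Ier3 at 1.47, Junb at 0.0733, Ntrk2 at −0.40, Olig2 at 0.0371, Phlda1 at −0.26 and Spry1 at 1.07. In that setting 2662 hGFAP-Cre cells (22.1%) lay in clusters with most raised markers of astrocytes that stayed unnamed, and with doublets kept 2291 (17.4%). At resolution 0.5, astrocyte-like cells were at −0.66 and, reversed, −0.0134. With values centred per library they were at −1.05 and 0.31, and interneuron lineage-like cells at −1.01 in the hGFAP-Cre mutant. With each library clustered alone, precursors were at 0.63 and 0.65, astrocyte-like cells at 0.00311 (reversed) and 0.90, interneuron lineage-like cells at −2.46 and −0.20, and upper-layer projection neuron-like cells, reversed, at 1.17 and 0.64. With cells called 1 by 1, precursors were at 0.45 and 0.52, astrocyte-like cells at −0.39 and, reversed, −0.0317, and interneuron lineage-like cells at −2.69 and −0.92. Taking radial glia-like with astrocyte-like clusters moved nothing with the main choices, because no cluster was named radial glia-like. With 1 UMI floor (added), precursors were at 1.49 and 1.48, astrocyte-like cells at −0.39 in the Emx1-Cre mutant, and interneuron lineage-like cells at −3.52 and −0.90. With naming by mean fold (added), astrocyte-like cells were, reversed, at 0.68 and −2.94 (−0.57 and 0.08 with radial glia), and interneuron lineage-like cells, reversed, at 0.83 and 3.10 (−3.51 and −0.91 with cortical interneurons). Without Cajal-Retzius-like and ependymal-like cells (added), astrocyte-like cells were at −0.24 and 0.15 and interneuron lineage-like cells at −3.51 in the Emx1-Cre mutant. Precursor-like and multipotent progenitor-like cells together (added) were, reversed, at −1.02 and −0.52. The hGFAP-Cre ERK response median was −1.57 with a pseudocount of 1 CPM, −0.67 with 20 CPM and −1.50 for members at 50 CPM or more, where BMP and ID genes were reversed at 0.28. Over all detected members it was −0.0458 and −0.74, and the Emx1-Cre interferon response list was reversed at −0.0280. In cells thinned to 2000 UMIs the Emx1-Cre p53 and apoptosis list was reversed at −0.13. In cells without Mki67 and Top2a counts the ERK response list was at −0.20 and −1.41.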

Other observations

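The test of regional origin was chosen after the result was seen; that of cycling cells was set before.

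Within oligodendrocyte precursor-like cells the oligodendrocyte lineage list was lower in both mutants than in the control, with medians of −0.62 (percentile 0.02) in the Emx1-Cre and −0.59 (percentile 0.02) in the hGFAP-Cre mutant and 7 of 14 members lower in each. The receptor tyrosine kinase list was at −0.26 (percentile 27.7) and −0.72 (percentile 0.41) in these cells, and the control's 65 cells set the precision. Microglia-like cells, outside both Cre lineages, had lower G2/M phase genes in both: the medians were −1.38 with 18 of 20 members lower in the Emx1-Cre and −0.74 with 13 of 20 lower in the hGFAP-Cre mutant. Of the other cells outside these lineages, endothelial-like and mural-like cells had G2/M medians of −0.60 and −0.27 in the Emx1-Cre and −2.90 and −2.61 in the hGFAP-Cre mutant, with fewer cells. The microglia-like class differs in makeup, as 61.5% of Emx1-Cre and 25.9% of hGFAP-Cre microglia-like cells lay in a cluster with 0 control cells. Of its G2/M phase genes, 13 were lower in both, against 11.7 for independent lists and 0.01 for unchanged libraries simulated against the shared control, and part of this can come from that control.

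The ERK response list was lower in astrocyte-like cells of the hGFAP-Cre mutant and near other genes in the Emx1-Cre mutant. A hypothesis that fewer cycling cells in the hGFAP-Cre class account for this was tested in cells with no UMI of Mki67 and Top2a, where the hGFAP-Cre median was −1.41, lower than the −1.23 in all cells, which argues against it. A second hypothesis is that the Emx1-Cre astrocyte-like cells may come in part from regions outside the pallium, which Emx1-Cre would not have recombined. The dissection of dorsal cortex speaks against it. The sort says little here even if tdTomato is a Cre reporter. Cells outside the Cre lineages, such as microglia-like cells at 2.02%, were present in the Emx1-Cre library. Genes of the pallium and telencephalon, a list of 8 written after the main results were seen, were low in the Emx1-Cre astrocyte-like cells (percentile 0.02), with Lhx2 at 89.9 against 400.3 CPM and Emx1 at 3.72 against 43.1 CPM, while Emx1 was at 83.6 in the hGFAP-Cre cells. The Emx1-Cre library carries a Cre driven by Emx1 whose construct is not given, so its Emx1 level may not reflect regional origin. The same list was also low in the hGFAP-Cre cells (percentile 1.97), where it was predicted not to be, so the hypothesis stays open. Lists of diencephalic and midbrain and of subpallial progenitor genes, written at the same time, had fewer than 3 members at 10 CPM and gave no median; of their genes Six3 was at 11.95, En1 at 5.67 and Otx2 at 5.43 CPM in the Emx1-Cre cells, against 0.0445, 0 and 0 in the control, En1 and Otx2 under the 10 CPM minimum, while Zic2 was at 10.55 against 38.2 and Zic1 at 15.4 against 15.6. Single clusters of the class, looked at after these results, differed: the Emx1-Cre medians over the control's class were −0.36, −0.16 and −2.06 in clusters of 774, 1067 and 150 cells, and the hGFAP-Cre medians −1.65 and −2.13 in clusters of 2072 and 849 cells. The 150 Emx1-Cre and 849 hGFAP-Cre cells belonged to the same cluster, where the medians were alike. The cluster with 774 Emx1-Cre cells had mitotic genes such as Ube2c and Birc5 on top. The class median of a library thus depends on which clusters it holds.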
